A study of Danio rerio with 23 samples.

How the data were processed

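Total RNA of whole zebrafish embryos was measured on Agilent single-colour arrays in 2 genotypes at 3 times. Knock-out (KO) embryos came from a line deficient in miR-223, made with CRISPR/Cas9 guides against the microRNA's precursor and bred to homozygosity. Wild type (WT) embryos served as controls. Embryos were collected at 0, 1 and 6 h on a scale the labels call hpw, which is taken here, from knowledge of the study, as hours post wounding. Each of the 6 groups held 4 arrays, except KO at 1 h with 3, which has no replicate 1. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates were separate clutches or animals, so every p-value measures only the spread between these samples, which may be partly technical.

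RNA was extracted with Trizol, cleaned on a column and labelled with Cy3 by a low-input amplification kit, per the labels' protocols. Images were read with Agilent Feature Extraction 11.5, per the submitters' processing notes, and the file headers give version 11.5.1.1. The processed signal of each spot is a linear intensity from which the background was subtracted with spatial detrending, per the file headers, and it was not normalized between arrays. Median spot and median local background intensities, also per the file headers, are raw pixel values. The deposited value table holds the same processed intensity rounded to 3 digits. Over 180880 spots of each array the largest relative difference from the scanner values was 0.498%, so its scale is linear, with no centring and no ratio whose direction stays unknown. Column medians of that table were 96.7, 104, 489 and 112 for replicates 1 to 4 of WT at 0 h, 102, 119, 137 and 143 for WT at 1 h, and 131, 152, 154 and 135 for WT at 6 h. For KO they were 102, 115, 120 and 109 at 0 h, 105, 127 and 133 for replicates 2 to 4 at 1 h, and 123, 154, 140 and 128 at 6 h. The authors also deposited probe lists of KO against WT at each time with log2 fold changes, made in GeneSpring per the series' design text, holding probes of at least 1.5-fold. Their test and any threshold on p are not given in the sources used here.

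Each array carries 176026 non-control spots of 128291 probes and 4854 control spots. Probes were named through RefSeq accessions, without versions on both sides, in a gene table of assembly GRCz12tu, which was used for names, chromosome numbers and gene order only. Of 42900 probes with such an accession 39952 matched, giving 13547 genes, and 88339 probes kept the accession or contig of the array design. For each array, log2 of the processed signal was taken minus the array's 75th percentile over non-control spots. Control spots and spots with outlier flags were left out and the spots of a probe averaged. A probe counted as well above background on an array where at least 0.5 of its spots carried that flag, and probes so on at least 3 arrays were kept, 100615 in number. A further 1207 of these had no usable spot on some array and were left out, leaving 99408. Per gene name or accession the probe with the highest mean was tested, in all 63986 features, of which 13171 were named genes. These features are called genes in what follows.

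The test was limma 3.58.1 in R 4.3.3 on group means of all 23 arrays, with empirical Bayes moderation, two-sided p-values and Benjamini-Hochberg adjustment within each comparison. A gene passed at an adjusted p under 0.05. Errors beside log2 differences are standard errors (SE) of that model. The comparisons were KO against WT at each time, 1 h and 6 h against 0 h in each genotype, and the difference between the genotypes in each of those responses. A probe not well above background on any array of a group has only a bound there. Its fold is given as at least the bright group's mean over the mean, per array of the dim group, of the higher of the probe's own value and the lowest signal among probes well above background. This bound allows for dim signal only and not for the spread between arrays, which the SE gives. Where the probe's own values lie above that lowest signal, the bound equals the measured fold.

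Genes are named by a fixed rule. For KO against WT and for the times it takes up to 10 genes with the highest and 10 with the lowest log2 difference among those with a gene symbol that passed and whose groups did not overlap. Where fewer than 5 passed, the 5 lowest p-values are given and said not to pass. The rule adds up to 4 members of each list and, wherever measured, cul1a, cul1b, traf6, tab1, il1b, cxcl8a, tnfa, mmp9, mmp13a and miR-223. No probe was matched to tab1, cxcl8a, mmp13a or miR-223 by accession, so these are not analysed here. Other genes named are said to have been chosen after their values were seen.

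The gene lists numbered 20: study targets, NF-kB components and feedback, cytokines and chemokines, immediate early genes, JAK-STAT signalling, matrix proteases and wound matrix, complement and acute phase, neutrophil, macrophage and keratinocyte markers, interferon response, heat shock and unfolded protein response, cell cycle, skeletal muscle, eye and lens, digestive organs, erythroid, circadian clock, glucocorticoid response, and wound epidermis and regeneration. Most came from textbook markers, and the study targets are genes the study is known to have followed up. Each was tested in the 9 comparisons with limma's camera at a preset correlation of 0.01, adjusted over all 180 pairs. An estimated correlation and fry (statmod 1.5.0) were alternatives. The model, the comparisons, the lists, the naming rule and the alternatives were fixed before the data were examined, apart from those said to have been chosen after seeing the data.

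Alternatives were normexp background correction (offset 50), quantile normalization, median centring, other filters on dim probes, the mean of a gene's probes, blocks for replicate number and slide, array weights, an intensity trend, fits of the compared groups alone, the deposited value table, a 2-fold minimum, and leaving out each array. Mean spot signals were not used here, so normexp ran on the median spot and background signals. A test of miR-223 seed sites was not run because transcript sequences were not used here. Added after seeing the data were all results without replicate 3 of WT at 0 h other than those of leaving out each array in turn, a replicate block within genotype, the named genes as background or as the only genes adjusted over, and combinations of these.

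Slides and scan days were read from the scanner files. Each time had 2 slides of its own and each slide held both genotypes, replicates 1 and 2 on one and 3 and 4 on the other. On every slide WT arrays lay at positions 1 and 3 and KO arrays at positions 2 and 4, so genotype cannot be told apart from position on the slide. Slides 1 to 3, among them both slides at 0 h, were scanned on day 1 and slides 4 to 6 on day 2, so 6 h against 0 h cannot be told apart from scan day. Because each slide held a single time, slide entered the comparisons of genotypes as a fixed block and those of times as a random block, with a consensus correlation of 0.095. Replicate numbers paired the samples over time in KO, where the deviations of same-numbered arrays from their group means correlated at 0.40 to 0.49 between 1 h and 0 h and at 0.24 to 0.44 between 6 h and 0 h. The pairing comes from the data, since the labels give only the number. In WT these values were −0.03 to 0.34 and 0.06 to 0.32, and between genotypes they lay between 0 and 0.25 at the 3 times, so there the numbers were not taken to pair samples with all arrays. The low values in WT come from replicate 3 at 0 h, without which they were 0.32 to 0.44 and 0.26 to 0.39. Between 1 h and 6 h in WT they were 0.27 to 0.37, and between genotypes at 0 h 0.14 to 0.37. The numbers may therefore pair samples in WT too, and results that rest on their independence are given with that limit. Same-numbered KO and WT arrays of a time also share a slide.

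Among 253 pairs of arrays at most 0.0028% of spots held the same value, and no array was a copy of another. The pipeline was tested on simulated data drawn for the 63986 genes. For KO against WT at 0 h it recovered 42% of genes changed by 1 on the log2 scale and 77% of those changed by 2, with 6 false calls, and at 1 h 37% and 72%, with 5. For 1 h against 0 h it recovered 50% and 77% in WT, with 17 false calls, and 33% and 76% in KO, with 9. Of the 20 lists, the 1 that was shifted in the simulation was found and 0 of the others passed with camera. The simulated genes were independent of each other and no simulated array stood apart. The simulation therefore does not show how the list test behaves on correlated genes or with such an array. Gene order on a chromosome was tested with 100000 permutations. Tables were handled with data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9 under Python 3.11.15.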

Results

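Expression was profiled in zebrafish embryos lacking miR-223, a microRNA abundant in myeloid cells such as neutrophils, and in wild type embryos, at 0, 1 and 6 h after wounding. The groups held 4 arrays each, except KO at 1 h with 3. The design addresses what the loss of miR-223 changes at each time, how each genotype responds over time, and whether the responses differ.

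Of the non-control spots, 68.5% to 77.4% were well above background on all arrays but replicate 3 of WT at 0 h, where the share was 99.1%. That array had a median signal of 503.3 against 104.7 to 167.6 on the others, and its 75th percentile was 1448 against 765.4 to 1194.2. No array had a saturated spot. Its rank correlation with the other arrays of its group was 0.812 to 0.818, while any other 2 arrays of the series correlated at 0.969 to 0.99 across spots, which are not independent replicates. The array was kept in the fit, and counts without it, chosen after seeing the data, stand beside each result. Under the 75th percentile scaling it moved the median log2 difference of all genes to −0.14 in KO against WT at 0 h, to −0.13 in WT at 1 h against 0 h and to −0.10 in WT at 6 h against 0 h. Quantile normalization turned these medians to 0.11, 0.08 and 0.10, and without the array they were 0.01, −0.02 and 0.01. Medians of the differences in response were 0.10 at 1 h and 0.09 at 6 h, and −0.10 and −0.11 with quantile normalization. Within slides the median of all genes in KO against WT was −0.26 on the slide of replicates 3 and 4 at 0 h, which holds that array, and −0.05 to 0.02 on the others. List medians are to be read against these values. The number of arrays limits the precision: the median SE over named genes was 0.17 to 0.18 for a comparison of 2 groups, and 0.24 and 0.23 for the differences in response at 1 h and 6 h.

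**Figure D1:**
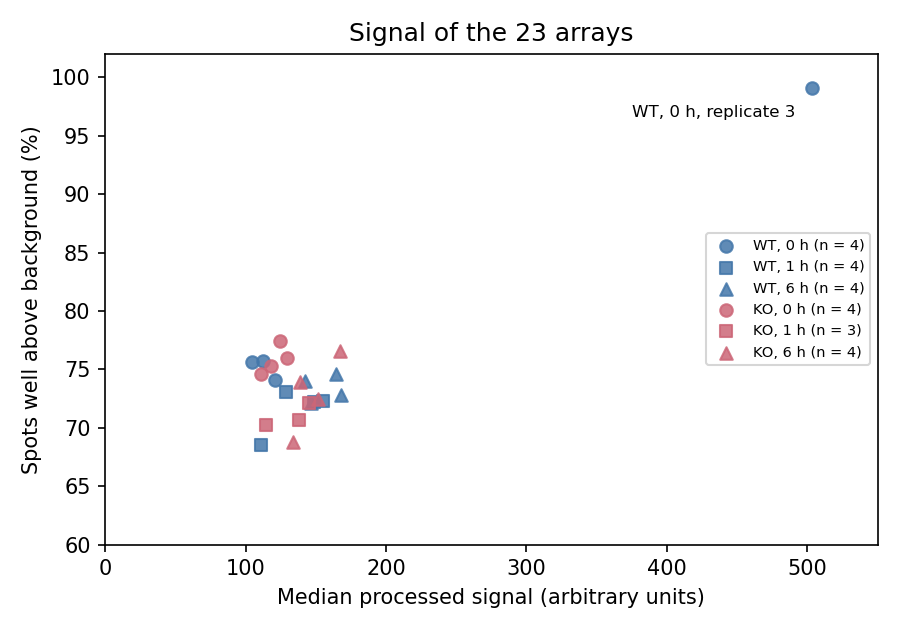
Share of non-control spots well above background (percent, vertical axis) against the median processed signal (arbitrary units, horizontal axis), 1 point per array, coloured by genotype and shaped by time. Replicate 3 of WT at 0 h lies at 99.1% and 503.3, and the other arrays lie between 68.5% and 77.4%.

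The knocked-out microRNA was not measured under a matched accession, so it gives no check of the labels. Genes that passed in KO against WT at both 1 h and 6 h, 80 in number, were used instead on the arrays at 0 h. The 0 h arrays entered that choice only through the shared spread, which favours genes that are steady on them. The KO arrays at 0 h lay nearer the WT level in 0% to 1.2% of these genes and the WT arrays in 93.8% to 100%, the lowest being replicate 3.

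At 0 h a small group of genes was far lower in KO embryos. The transcript of ms4a17a.9, from the MS4A family of membrane proteins, was tested by 1 probe only. Its signal was not well above background on any KO array and was at least 325-fold lower than in WT, or 309-fold without replicate 3 of WT at 0 h (fitted log2 difference −8.66 ± 0.33 (SE), n = 4 and 4, adjusted p = 1.42e-11). A part of the AP-1 transcription factor, junbb, was lower by a log2 difference of −6.77 ± 0.38 (adjusted p = 3.69e-09). It was well above background on only 1 of 4 KO arrays, so the size of this difference is uncertain. Lower too were ahsa1a, a co-chaperone that activates Hsp90 (−3.26 ± 0.27, adjusted p = 1.3e-06), and ms4a17a.16 (−2.67 ± 0.41, adjusted p = 0.00279). Genes higher in KO were led by tigarb, a phosphatase that restrains glycolysis (1.21 ± 0.17, adjusted p = 0.000881), and included the DNA replication clamp pcna (1.01 ± 0.17, adjusted p = 0.00712) and dhfr, which supplies folate for nucleotide synthesis (0.89 ± 0.14, adjusted p = 0.00358).

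The remaining genes that the rule named at 0 h were lower by −1.77 for the phosphatase ppm1f, −1.60 for the actin-processing protease actmap, −1.49 for the tight-junction protein cldn26, −1.46 for mal2, −1.41 for dmrt1 and −1.02 for nt5e, which makes extracellular adenosine. Higher were the junctional adhesion molecule f11r.2 (1.15), vac14 of a phosphoinositide kinase complex (1.07), the ribosome biogenesis factor imp4 (1.03), the mitochondrial phosphatase pgam5 (0.96), the pyruvate carrier mpc2a (0.94), cyp2x8 (0.90) and echdc1 (0.82). Their adjusted p-values ran from 0.000434 for mpc2a to 0.037 for dmrt1. Another probe of junbb gave −5.88 and the other probes of ms4a17a.16 a median of −2.38. Of the genes higher in KO, the other probes gave −0.39 for imp4, 0.04 for pgam5, 0.12 for vac14 and 0.42 for f11r.2, but 0.97 for pcna and 0.84 for cyp2x8. No other probe was tested for tigarb, mpc2a, ppm1f or mal2. In limma's test 202 genes passed at 0 h, 41 of them named, with 53 higher and 149 lower in KO. All 202 had the same direction on both slides, which is nearly given, since the same slides chose them. Within a slide 33 and 101 genes passed, 27 and 57 of them among the 202. With slide as a block 234 passed, 185 of them among the 202. Without replicate 3 of WT at 0 h 191 passed, 60 higher and 131 lower, of which 150 were among the 202, and ppm1f (adjusted p = 0.0526) and dmrt1 (adjusted p = 0.0913) did not. Leaving out replicate 1 or 4 of KO at 0 h left 108 or 106 genes, and the split into higher and lower was 60 and 84 with normexp and 41 and 70 with quantile normalization.

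**Figure D2:**
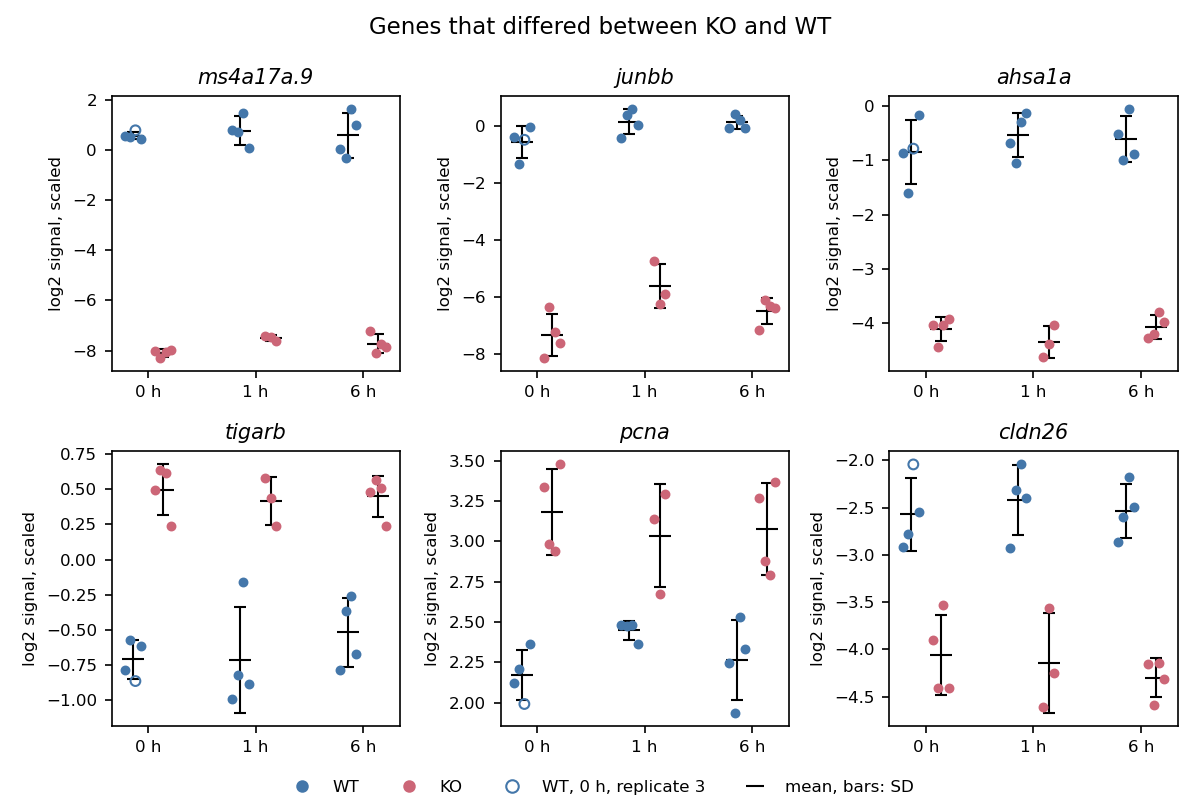
Log2 processed signal minus the array's 75th percentile (vertical axis, log2 units) at 0, 1 and 6 h (horizontal axis) for 6 genes. Points are arrays of WT and KO, horizontal bars the group means and whiskers the SD (n = 4, and 3 for KO at 1 h), and the open point is replicate 3 of WT at 0 h. All KO arrays lie below all WT arrays for ms4a17a.9, junbb, ahsa1a and cldn26, and above them for tigarb and pcna, although pcna passed only at 0 h (adjusted p = 0.0595 at 6 h).

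At 1 h the same 4 genes led those lower in KO. The log2 difference was −8.26 ± 0.35 for ms4a17a.9 (n = 3 and 4, adjusted p = 1.38e-10), at least 308-fold, −5.78 ± 0.41 for junbb (adjusted p = 1.9e-07), and −3.82 ± 0.29 for ahsa1a (adjusted p = 5.42e-07). The tested probe of ms4a17a.16 was not well above background on any KO array and was at least 7.06-fold lower (fitted log2 difference −2.82 ± 0.44, adjusted p = 0.00584). As junbb was well above background on 2 of 3, the size of its difference is uncertain here too. Others lower in KO were cldn26 (−1.72), mal2 (−1.42), the lysosomal sulfatase gnsb (−1.13), the G protein subunit gnb2 (−1.05), the protease inhibitor serpinb1l2 (−1.04) and nt5e (−1.01). Higher were tigarb (1.13 ± 0.18, adjusted p = 0.0066), imp4 (1.04), dhfr (1.00 ± 0.15, adjusted p = 0.00377), vac14 (0.89) and cnppd1 (0.61). Another probe of ahsa1a gave −3.32, the other probes of dhfr had a median of 0.36, and those of cnppd1 had a median of 0.06 at 0 h. For serpinb1l2 no other probe was tested. In limma's test 91 genes passed at 1 h, 18 of them named, with 12 higher and 79 lower. All 91 had the same direction on both slides, which also chose them. The first slide held a single KO array, and on the other 24 genes passed, 22 of them among the 91. With slide as a block 97 passed, 81 of them among the 91. Without replicate 3 of WT at 0 h, which enters here only through the shared spread, 159 passed and included all 91. The count was 47 without replicate 2 and 56 without replicate 4 of KO at 1 h, 57 without replicate 1 and 60 without replicate 4 of WT at 1 h, and 50 with normexp, 12 higher and 38 lower.

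At 6 h ms4a17a.9 remained not well above background in KO and at least 313-fold lower (−8.30 ± 0.33, n = 4 and 4, adjusted p = 3.06e-11). Again lower were junbb (−6.60 ± 0.38, adjusted p = 5.76e-09), ahsa1a (−3.46 ± 0.27, adjusted p = 6.79e-07), ms4a17a.16 (−2.59 ± 0.41, adjusted p = 0.00485), cldn26 (−1.77), ppm1f (−1.64), mal2 (−1.40), gnsb (−1.23), serpinb1l2 (−1.18) and nt5e (−0.96). Both junbb and ms4a17a.16 were well above background on 1 of 4 KO arrays, so the sizes of their differences are uncertain. Higher in KO were tigarb (0.97 ± 0.17, adjusted p = 0.012), imp4 (0.89), echdc1 (0.86), cyp2x8 (0.81), dhfr (0.80), cnppd1 (0.59) and decr1, which degrades unsaturated fatty acids (0.58). The other probes of cldn26 had a median of −1.89, and those of gnsb a median of −0.13. In limma's test 124 genes passed at 6 h, 20 of them named, with 21 higher and 103 lower. All 124 had the same direction on both slides, which also chose them. Within either slide 24 genes passed, 21 and 24 of them among the 124. With slide as a block 128 passed, 110 of them among the 124. The genes that passed without replicate 3 of WT at 0 h numbered 202 and included all 124. The count was 71 without replicate 4 of KO at 6 h, 75, 82 and 82 without replicates 1, 2 and 4 of WT at 6 h, and 66 with normexp, 18 higher and 48 lower.

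Much of the difference between genotypes was shared by the times, which have no arrays in common. Of the genes that passed, 79 did so at both 0 h and 1 h, 105 at both 0 h and 6 h and 80 at both 1 h and 6 h, all in the same direction. Independent lists of these sizes would share at most 0.017 higher and 0.24 lower genes, although the spread of each gene, estimated over all arrays, enters every comparison and raises such overlaps. WT arrays lay at positions 1 and 3 of each slide and KO arrays at 2 and 4, so a difference between positions would be shared by the times as well. At all 3 times 76 genes passed, 67 lower and 9 higher in KO, 13 of them named, out of 229 that passed at any time. When replicate 3 of WT at 0 h was left out 108 passed at all times, 90 lower and 18 higher.

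Cell cycle genes as a list were higher in KO at each time. All 30 measured members had a positive difference at 0 h, with a median of 0.44 against −0.14 for all genes (camera, adjusted p = 3.15e-20), and 29 did so at both 1 h (median 0.19, adjusted p = 2.77e-06) and 6 h (median 0.14, adjusted p = 2.77e-06). These calls were lost at each time, with adjusted p = 0.381, 0.643 and 0.643 with an estimated correlation. Of single members pcna passed over all genes at 0 h. When adjusted over the list alone 4 passed at 0 h, namely pcna, the helicase subunit mcm3 (0.55 ± 0.15) and the mitotic cyclins ccnb2 (0.59 ± 0.18) and ccna2 (0.58 ± 0.19), and 1 at 6 h, pcna (0.81 ± 0.17). Within slides the median was 0.38 and 0.51 at 0 h (all genes 0.01 and −0.26), 0.35 and 0.06 at 1 h (−0.02 and 0.02), and 0.26 and 0.05 at 6 h (−0.05 and 0.02). Digestive organ genes were at −0.70 and −1.20 on the slides where the list was at 0.35 and 0.26, and eye and lens genes at −0.13 and −0.79. On the slides where the cell cycle list was at 0.06 and 0.05 digestive organ genes were at 0.06 and 0.03. At 0 h digestive organ genes were at −1.60 where it was at 0.38, but at −0.26, as all genes were, where it was at 0.51. With slide as a block the adjusted p of the cell cycle list was 1.83e-17, 0.000198 and 2.1e-05. The median at 0 h without replicate 3 of WT at 0 h was 0.30, with an adjusted p of 2.16e-10.

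Complement and acute phase genes were higher in KO too, in 13 of 18 measured members at 0 h (median 0.38 against −0.14 for all genes, adjusted p = 6.29e-06), 12 at 1 h (median 0.21, adjusted p = 0.013) and 13 at 6 h (median 0.14, adjusted p = 0.0382). With an estimated correlation the adjusted p was 0.372, 0.643 and 0.643. When adjusted over the list alone 6 members were higher at 0 h, among them c3a.1 (0.63 ± 0.14), cfb (0.67 ± 0.18) and cp (0.64 ± 0.18), and 1 was lower. At 1 h cp alone passed on that basis. Within slides the medians were 0.28 and 0.50 at 0 h (all genes 0.01 and −0.26), 0.32 and 0.15 at 1 h and 0.18 and 0.18 at 6 h. Digestive organ genes, among them genes of the liver, were at −1.60 and −0.70 on the slides where complement genes were at 0.28 and 0.32, and at 0.06 where these were at 0.15. The other slides did not follow this. Digestive organ genes were at −0.26, as all genes were, where complement genes were at 0.50, and at −1.20 and 0.03 at 6 h. The call at 0 h was lost with quantile normalization (adjusted p = 0.1) and the call at 1 h against the named genes (0.0537). The call at 6 h was lost with slide as a block (0.0609), with replicate number as a block (0.13) and against the named genes (0.0993).

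Erythroid genes were higher in 17 of 21 members at 0 h (median 0.37 against −0.14 for all genes, adjusted p = 2.7e-06), 18 at 1 h (median 0.14, adjusted p = 0.0107) and 18 at 6 h (median 0.21, adjusted p = 0.00116), with no member passing by itself. The anion exchanger slc4a1a had a difference of 0.98 ± 0.35 at 0 h and the globin hbbe2 one of 0.67 ± 0.27. With an estimated correlation the adjusted p was 0.401, 0.643 and 0.595, and without replicate 3 of WT at 0 h it was 0.0506 at 1 h, where it was 0.0536 against the named genes. Within slides the medians were 0.44 and 0.40 at 0 h (all genes 0.01 and −0.26), 0.20 and 0.15 at 1 h and 0.41 and 0.15 at 6 h. Digestive organ genes were at −1.60 and −1.20 on the slides where erythroid genes were at 0.44 and 0.41, and at 0.06 and 0.03 on those where both values were 0.15. Where erythroid genes were at 0.40, however, digestive organ genes were at −0.26, as all genes were, and at −0.70 where erythroid genes were at 0.20. Eye and lens genes were lower in KO at 6 h, in 26 of 35 members (median −0.49, adjusted p = 0.0339), with medians of −0.79 and −0.23 within slides. That adjusted p was 0.643 with an estimated correlation and 0.117 without replicate 3 of WT at 0 h. At 0 h the list did not pass with all arrays (median −0.39 against −0.14, adjusted p = 0.509). It was lower in KO there with quantile normalization (adjusted p = 6.75e-05), against the named genes (0.0127) and without replicate 3 of WT at 0 h (median −0.76, adjusted p = 0.00124). Its medians within slides were −0.83 and −0.40, against 0.01 and −0.26 for all genes, and its adjusted p at 0 h with an estimated correlation was 0.874.

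A few genes were higher at 1 h than at 0 h in WT. The AP-1 gene fosab, an immediate early gene, rose by 1.97 ± 0.26 on the log2 scale (n = 4 and 4, adjusted p = 0.00544), the clock gene per1b by 1.58 ± 0.21 (adjusted p = 0.00544) and the carboxylate transporter slc16a9b by 1.19 ± 0.14 (adjusted p = 0.00147), while lingo4a fell by 1.11 ± 0.17 (adjusted p = 0.0249). With the next lowest p-value, dhrs13a.2 had a difference of 1.25 ± 0.22 and did not pass (adjusted p = 0.0509). In limma's test 11 genes passed, 8 higher and 3 lower at 1 h, with 10 and 0 under normexp and 9 and 1 under quantile normalization. Without replicate 3 of WT at 0 h 21 passed, 10 of them among the 11, and the count was 36 without replicate 4 of WT at 0 h and 21, 63 and 5 without replicates 1, 2 and 3 of WT at 1 h. With slide as a random block 8 passed. With limma on the compared groups alone 0 genes passed, and 2010 had an unadjusted p under 0.05. With limma and the probes of a gene averaged these numbers were 0 and 7918, against 7765 in the fit of all arrays and 3840 without replicate 3 of WT at 0 h.

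In KO the same 3 named genes rose at 1 h: fosab by 2.46 ± 0.28 (n = 3 and 4, adjusted p = 0.00105), per1b by 1.47 ± 0.22 (adjusted p = 0.0265) and slc16a9b by 1.03 ± 0.15 (adjusted p = 0.0215). The next lowest p-values, which did not pass, were those of lingo4a (−1.06 ± 0.19, adjusted p = 0.1) and the stress-induced factor atf3 (0.85 ± 0.17, adjusted p = 0.17). Without replicate 3 of WT at 0 h both passed in limma's test (adjusted p = 0.023 and 0.0355). In limma's test 7 genes passed, 7 higher and 0 lower, and 2790 had an unadjusted p under 0.05, or 5998 without replicate 3 of WT at 0 h. Quantile normalization gave 6 higher and 2 lower, and median centring 7 and 3. Of the 11 genes of WT and the 7 of KO 6 were shared, where independent lists would share 0.0012, and all 12 that passed in either genotype had the same direction in both. WT and KO arrays of a time share slides, and each gene's spread enters both comparisons, which can raise this overlap. With replicate number as a block 4 genes passed, and with slide as a random block 4. There were 61 without replicate 3 of WT at 0 h, 17 higher and 44 lower, and leaving out single KO arrays gave 3, 2, 2 and 2 for replicates 1 to 4 at 0 h and 3 and 2 for replicates 2 and 4 at 1 h.

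As a list, immediate early genes were higher at 1 h in 32 of 35 members in WT (median 0.26 against −0.13 for all genes, adjusted p = 4.35e-14) and 29 in KO (median 0.27, adjusted p = 5.93e-14), with adjusted p = 0.219 in both with an estimated correlation. Against the named genes alone and without replicate 3 of WT at 0 h it was 0.0401 in WT and 0.0155 in KO with an estimated correlation, the only calls of the 180 in that setting. When adjusted over the list alone 5 members passed in WT, with atf3 (0.73 ± 0.15), the phosphatase dusp5 (0.49 ± 0.14) and ier2a (0.65 ± 0.19) beside fosab, and 7 in KO, dusp5 (0.51 ± 0.15) among them. Another of the 7 was junbb, well above background on only 1 of 4 KO arrays at 0 h and 2 of 3 at 1 h, so its rise there has no reliable size. Clock genes shifted up in WT (25 of 35 members, median 0.23 against −0.13, adjusted p = 4.72e-08) and KO (26 members, median 0.20, adjusted p = 2.6e-07), with 0.3 and 0.315 as adjusted p with an estimated correlation. On the list alone 4 rose in WT, among them per1b, cry2 (0.48 ± 0.13) and nr1d2a (0.94 ± 0.28), and per3 was lower (−0.44 ± 0.12), while per1b and nr1d2a (1.2 ± 0.30) rose in KO. Glucocorticoid-responsive genes shifted up in WT (15 of 19 members, median 0.21 against −0.13, adjusted p = 1.51e-06) and KO (13 members, median 0.15, adjusted p = 0.000912), with adjusted p = 0.287 and 0.372 with an estimated correlation. Adjusted over the list alone, pfkfb4b (0.90 ± 0.19) and the kinase sgk1 (0.49 ± 0.12) passed in WT, and fkbp5, a classical steroid target, had a difference of 2.11 ± 0.71.

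JAK-STAT signalling genes were shifted up at 1 h by less, with medians of 0.09 in WT, against −0.13 for all genes (12 of 19 members, adjusted p = 0.0029) and 0.04 in KO (13 members, adjusted p = 0.00867), and 0.315 and 0.353 as adjusted p with an estimated correlation. Against the named genes the call in WT was lost (0.14). The cytokine-induced inhibitor cisha passed when adjusted over the list alone in WT (0.65 ± 0.14) and KO (0.59 ± 0.15), and socs3a had differences of 0.55 ± 0.17 and 0.59 ± 0.19. Genes of the NF-kB list shifted up in WT (13 of 20 members, median 0.11 against −0.13, mean −0.02, adjusted p = 0.00475, and 0.0765 without replicate 3 of WT at 0 h) and KO (11 members, median 0.05, adjusted p = 0.0175). Their adjusted p with an estimated correlation was 0.372 and 0.419, and in WT it was 0.197 with quantile normalization and 0.207 against the named genes. The inhibitor nfkbiaa had differences of 0.65 ± 0.21 in WT and 0.59 ± 0.23 in KO, and neither passed.

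Other lists moved at 1 h in KO. Cell cycle genes were lower than at 0 h in 28 of 30 members (median −0.18, adjusted p = 0.00142), eye and lens genes higher in 33 of 35 (median 0.49, adjusted p = 0.00196), and heat shock and unfolded protein genes lower in 22 of 30 (median −0.11, adjusted p = 0.0101). With an estimated correlation the adjusted p was 0.732, 0.589 and 0.71, and heat shock genes were at 0.0526 without replicate 3 of WT at 0 h. Adjusted over the heat shock list alone, serpinh1a (−0.91 ± 0.23) and serpinh1b (−0.97 ± 0.26), chaperones of collagen, passed. In WT at 1 h, matrix, complement, keratinocyte, cell cycle, skeletal muscle and erythroid lists also shifted up, with adjusted p = 0.00411, 0.0389, 0.000897, 0.000843, 0.00411 and 0.0469. Of these, 5 lost the call without replicate 3 of WT at 0 h and the muscle list turned down (adjusted p = 0.012), and with an estimated correlation the adjusted p was 0.353, 0.643, 0.643, 0.732, 0.732 and 0.732.

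**Figure D3:**
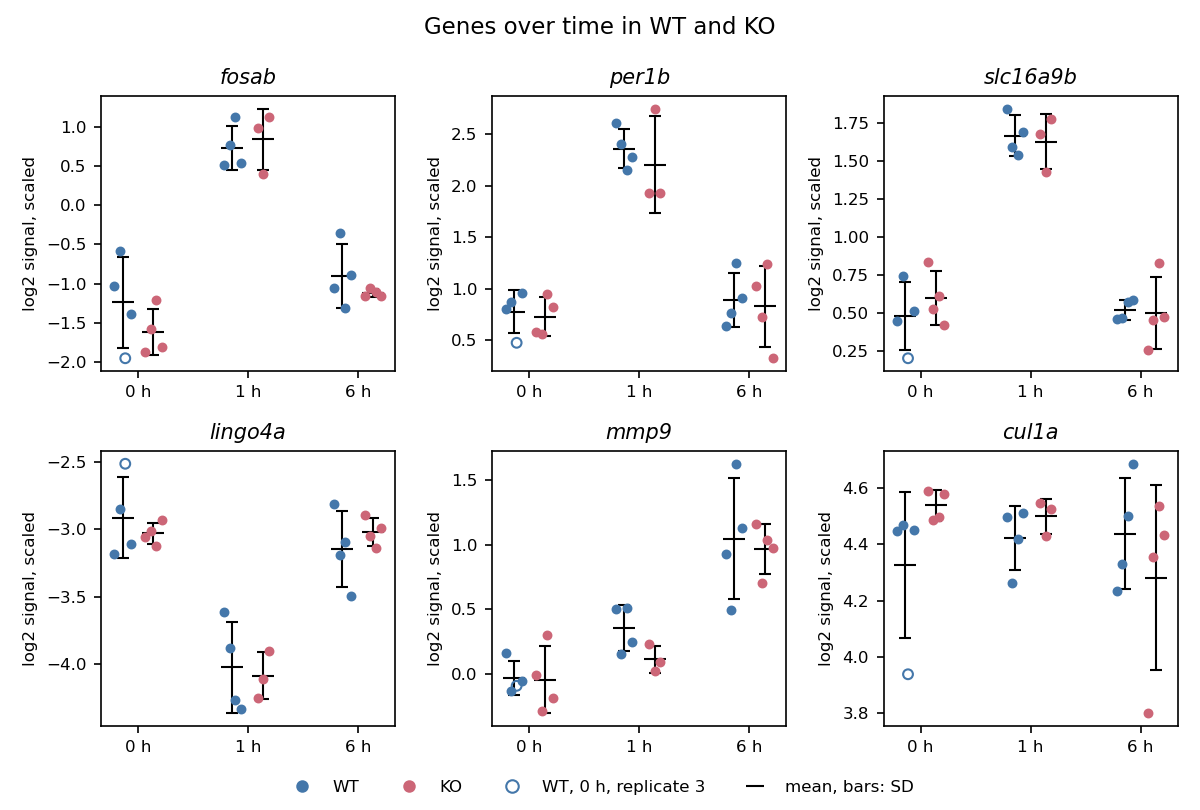
Log2 processed signal minus the array's 75th percentile (vertical axis, log2 units) at 0, 1 and 6 h (horizontal axis) for 6 genes in WT and KO. Points are arrays, horizontal bars the group means and whiskers the SD (n = 4, and 3 for KO at 1 h), and the open point is replicate 3 of WT at 0 h. At 1 h fosab, per1b and slc16a9b are higher in both genotypes, and mmp9 is highest at 6 h, by 1.07 in WT and 1.01 in KO over 0 h, without passing over all genes in the fit without a block.

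At 6 h the wound protease mmp9 had the lowest p-value of the named genes in WT (1.07 ± 0.18, n = 4 and 4, adjusted p = 0.294) and nearly the same difference in KO (1.01 ± 0.18, adjusted p = 0.46). It passed neither test over all genes in the fit without a block, but when adjusted over the list of matrix proteases alone it passed in both genotypes (adjusted p = 0.000345 and 0.00072). With replicate number as a block within genotype and without replicate 3 of WT at 0 h, chosen after seeing the data, mmp9 passed over all genes in KO (limma, 1.01 ± 0.14, adjusted p = 0.039) but not in WT. In WT the next were pth2 (−1.25 ± 0.27), the sodium exchanger slc9a3.1, stat3 of the JAK-STAT pathway (0.59 ± 0.14) and gli3 (0.38 ± 0.09), each with an adjusted p of 0.521. Not well above background at 6 h, slc9a3.1 was at least 4.87-fold lower there (fitted log2 difference −2.53 ± 0.59), or 2.97-fold without replicate 3 of WT at 0 h. In KO zc3h18 (−1.15 ± 0.20) had a lower p-value than mmp9, and those next after mmp9 were znf296 (−0.49 ± 0.09), the bone phosphatase phospho1 (−0.82 ± 0.16) and tln2a (−0.76 ± 0.16). Adjusted p-values of these 4 were 0.422 to 0.639. With limma 0 genes passed in WT and 0 in KO, and 5835 and 1680 had an unadjusted p under 0.05, where 3199 would by chance. These numbers were 3239 in WT and 4027 in KO without replicate 3 of WT at 0 h, so that array decides which genotype has the larger excess. Each 6 h array was scanned on the other day than the 0 h arrays, so time and scan day cannot be told apart here. Leaving out replicate 2 of WT at 0 h or of WT at 6 h gave 1 gene in WT, and replicate 3 of WT at 0 h or replicate 4 of KO at 6 h 1 gene in KO, where array weights gave 41.

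Among the lists at 6 h, KO embryos had lower values than at 0 h in heat shock genes (22 of 30 members, median −0.08, adjusted p = 0.00296), cell cycle genes (27 of 30, median −0.12, adjusted p = 0.00426), skeletal muscle genes (25 of 28, median −0.13, adjusted p = 0.00226) and keratinocyte markers (23 of 27, median −0.08, adjusted p = 0.0323). The collagen chaperone serpinh1a (−0.85 ± 0.21) passed when adjusted over the heat shock list alone. The adjusted p of these lists with an estimated correlation was 0.643, 0.766, 0.732 and 0.766. Quantile normalization turned the direction of the muscle and keratinocyte lists (adjusted p = 0.793 and 0.842) and ended the call of the heat shock list (adjusted p = 0.0621). In WT the immediate early, JAK-STAT, matrix, complement, cell cycle and glucocorticoid lists shifted up at 6 h, with adjusted p = 0.000338, 0.00748, 0.00188, 0.0464, 7.79e-06 and 0.0329. These became, without replicate 3 of WT at 0 h, 0.972, 0.129, 0.478, 0.565, 0.798 and 0.803, and with an estimated correlation 0.589, 0.353, 0.353, 0.643, 0.643 and 0.589.

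No gene was called with a different response in KO. With limma 0 genes passed at 1 h and 0 at 6 h, with 777 and 622 at an unadjusted p under 0.05 and smallest adjusted p-values of 0.981 and 0.949. Leaving out replicate 3 of KO at 1 h gave 1 gene at 1 h and leaving out replicate 4 of KO at 6 h 1 at 6 h. The lowest p-values at 1 h were those of zc3h18 (−0.97 ± 0.29), the kinase map3k7 of the NF-kB pathway (−0.41 ± 0.13), wrap53 (−0.46 ± 0.16), tmem86a (0.67 ± 0.24) and grm6a (1.01 ± 0.37). At 6 h they were those of the complement gene c3a.6 (−0.55 ± 0.18), the chemokine receptor cxcr3.2 (−0.47 ± 0.16), rmp24 (−0.39 ± 0.14), zc3h18 (−0.72 ± 0.28) and pias4b, whose tested probe was not well above background on any WT array at 6 h and so gave no usable value. The differences in response of fosab, per1b and mmp9 to time were not called either, and that of mmp9 at 6 h was −0.06 ± 0.26.

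Cell cycle genes as a list responded differently, with all 30 members lower in KO relative to WT at 1 h (median −0.26 against 0.10 for all genes, adjusted p = 3.05e-10). They were so at 6 h too (median −0.29 against 0.09, adjusted p = 6.87e-11). Both responses subtract the same difference between KO and WT at 0 h, and the list's higher level in KO at 0 h lowers both. For this and the other lists the times are therefore not separate observations. Without replicate 3 of WT at 0 h the medians were −0.11 (adjusted p = 0.0178) and −0.14 (adjusted p = 0.00699), with quantile normalization the adjusted p was 0.175 and 0.141, and with an estimated correlation it was 0.589 at both times. The matrix, complement, keratinocyte, heat shock, skeletal muscle and erythroid lists also shifted down at both times with all arrays, with adjusted p-values from 6.43e-05 to 0.0212. So did macrophage markers (adjusted p = 0.0218) and the glucocorticoid list (0.0412) at 1 h, and the immediate early (0.0297) and wound epidermis and regeneration (0.0448) lists at 6 h. With an estimated correlation their adjusted p was at least 0.353. These calls were lost without replicate 3 of WT at 0 h, except that of keratinocyte markers at 6 h, which turned up (adjusted p = 0.0284).

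In KO against WT at 0 h 4 further lists shifted up with all arrays: matrix proteases (adjusted p = 0.00961), keratinocyte markers (0.000387), heat shock genes (5.68e-06) and skeletal muscle (0.00255). With an estimated correlation the adjusted p was 0.372, 0.643, 0.589 and 0.732, and without replicate 3 of WT at 0 h it was 0.729, 0.723, 0.199 and 0.0744. Quantile normalization turned the muscle list down (adjusted p = 0.0137).

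In the fit without a block, with all arrays and all genes as background, 5 lists passed in none of the 9 comparisons. Their lowest adjusted p was 0.0724 for neutrophil markers (21 measured), 0.0909 for cytokines and chemokines (25), 0.566 for the interferon response (19), 0.117 for digestive organs (33) and 0.0761 for the study targets (3), a list taken from the study and so not independent of it. Neutrophil markers passed as lower in KO at 6 h without replicate 3 of WT at 0 h (17 of 21 members, median −0.15, adjusted p = 0.0363, and 0.0195 against the named genes), and with an estimated correlation these were 0.976 and 0.62. Their medians within slides were −0.14 and −0.16. Against the named genes without that array they also passed as lower at 1 h (0.0405) and in the response at 6 h (0.0472), and both were 0.711 with an estimated correlation. Digestive organ genes had a median of −1.01 in KO against WT at 0 h, against −0.14 for all genes, and passed as lower there against the named genes (0.0276) and without that array (0.0139, and 0.00817 with both). These calls were lost with an estimated correlation (0.932, 0.976 and 0.916). With replicate number as a block the list passed as lower in KO at 1 h (0.0294) and 6 h (0.022), where an estimated correlation without the block gave 0.791 and 0.805. Within slides their medians were −1.60, −0.70 and −1.20 at 0, 1 and 6 h on the slides of replicates 1 and 2 and −0.26, 0.06 and 0.03 on those of replicates 3 and 4, where all genes were at −0.26, 0.02 and 0.02. Cytokines passed against the named genes as lower in KO at 0 h (0.0319), as higher in KO at 1 h against 0 h (0.0439) and in the response at 1 h (0.028). The interferon list did so in the response at 6 h (0.0319). Each of these calls was lost with an estimated correlation (0.932).

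Of the 61 list calls 36 were lost or turned without replicate 3 of WT at 0 h, and 12 others passed only without it. Beside those of eye and lens and digestive organ genes at 0 h and of neutrophil markers at 6 h, these were the immediate early list, lower in KO at 0 h (adjusted p = 0.0075) and higher in the response of KO at 1 h (0.0142). Eye and lens genes were higher in that response too (5.04e-05, and 1.17e-05 with quantile normalization). Digestive organ genes were higher in the response at 6 h (0.038). In WT heat shock genes were lower at 1 h (0.0165) and 6 h (0.0284), as were keratinocyte (7.9e-06), skeletal muscle (1.38e-06) and digestive organ (0.02) genes at 6 h. With an estimated correlation the adjusted p of each was 0.976 without that array.

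Of the macrophage list, the chemokine receptor cxcr3.2 was higher in KO at 0 h (0.66 ± 0.11, adjusted p = 0.00732), with −0.03 for its other probe, and ms4a17a.4 was lower at 1 h (−0.86 ± 0.17, adjusted p = 0.0402), with a median of 0.01 for its other probes. Differences between KO and WT at 0, 1 and 6 h were 0.21 ± 0.15, 0.08 ± 0.16 and −0.16 ± 0.15 for cul1a, a scaffold of ubiquitin ligases, and 0.11 ± 0.11, 0.09 ± 0.12 and 0.02 ± 0.11 for cul1b. For traf6, an adaptor of NF-kB signalling, they were 0.23 ± 0.14, 0.18 ± 0.16 and 0.19 ± 0.14, and for mmp9 −0.02 ± 0.18, −0.24 ± 0.20 and −0.08 ± 0.18, and none passed (adjusted p at least 0.445). The cytokine il1b was well above background by any of its probes on 0 of 4, 0 of 3 and 1 of 4 KO arrays and on 1, 2 and 1 of 4 WT arrays at 0, 1 and 6 h, and tnfa on 2, 0 and 1 KO and 2, 1 and 0 WT arrays, so neither gave a usable comparison of levels.

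The authors' deposited table for KO against WT listed 1850 probes at 0 h, 640 higher and 1210 lower, 1719 at 1 h, 731 higher and 988 lower, and 1885 at 6 h, 859 higher and 1026 lower. Of these 1767, 1488 and 1538 were tested here as single probes, and 100% had the same direction as in the authors' deposited table. At each time the log2 differences of these probes correlated with the authors' at 1, with a slope of 1. Both come from the same arrays, so the same direction was given and is no independent check. With limma's adjusted p 305, 138 and 182 of them passed in that direction, which is 16.5%, 8% and 9.7% of the listed probes, and 1694, 954 and 1056 had an unadjusted p under 0.05. Without replicate 3 of WT at 0 h the numbers that passed were 248, 231 and 292.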

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

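Replicate 3 of WT at 0 h had been seen to stand apart before the tests of its causes in this part were chosen. What each cause predicts was written before its test was run, except for an added background, where it was written after. Within groups of 4 arrays, 425 sets of values of 83 genes and of 2 array measures were examined for a single array far from the other 3, where chance would flag about 1 in 20, or 21. The number found was 33, and 15 of them were in replicate 3 of WT at 0 h.

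On that array 99.1% of spots were well above background, against 74.1% to 75.7% on the others of its group, and the 75th percentile of the signal was 1448 against 765.4 to 860.4. Its scaled log2 values lay above those of its group for il1b (−0.16 against −7.37 to −6.64), tnfa (−0.53 against −7.15 to −6.04), npy1r (−2.50 against −6.05 to −5.55), slc9a3.1 (−2.31 against −5.34 to −4.92), dmrt1 (−0.85 against −2.12 to −1.93) and echdc1 (−1.47 against −2.01 to −1.94). They lay below for cul1a (3.94 against 4.45 to 4.47), c3a.1 (3.47 against 4.18 to 4.28), cnppd1 (0.58 against 1.00 to 1.07), wrap53 (−0.02 against 0.37 to 0.42), stat3 (−0.68 against −0.28 to −0.21), atf3 (−1.33 against −0.85 to −0.84) and jdp2b (−1.24 against −0.51 to −0.49).

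A different scanner gain or scaling leaves ranks as they are, yet the highest rank correlation of this array with its group was 0.818, below the lowest of 0.969 between any other 2 arrays. A background left on every spot after subtraction would raise the negative controls as well. In the processed signal these rose by 1.33, which is 0.361% of the rise of 368 in the median spot. Background had already been subtracted from that signal and raw signals were not compared, so a background removed by the subtraction is not addressed. A KO sample under a WT label would lie near KO, and the array lay nearer WT in 93.8% of the 80 genes that passed at 1 h and 6 h. The array entered the choice of these genes only through the shared spread. A difference in the amount or state of the RNA, or in labelling or hybridisation, may have raised dim probes in particular and stays open, and no biological explanation was tested.

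In the other arrays single values stood apart with no pattern by array. In KO these were f11r.2 in replicate 2 at 0 h (−0.30 against 0.29 to 0.34), vac14 in replicate 1 at 0 h (1.48 against 1.34 to 1.35) and dhrs13a.2 in replicate 4 at 0 h (0.61 against 0.90 to 0.93). At 6 h they were pgam5 in replicate 2 (3.01 against 3.27 to 3.33), slc9a3.1 in replicate 4 (−5.48 against −7.00 to −6.77), socs3a in replicate 4 (−0.73 against −0.40 to −0.35), cfb in replicate 3 (3.70 against 3.52 to 3.53), ms4a17a.4 in replicate 3 (−0.27 against 0.01 to 0.03) and kera in replicate 1 (−0.06 against −0.60 to −0.53). In WT they were traf6 in replicate 4 at 0 h (−2.05 against −2.48 to −2.45), pcna in replicate 4 at 1 h (2.36 against 2.48), echdc1 in replicate 3 at 1 h (−1.52 against −2.12 to −2.08), actmap in replicate 3 at 1 h (−3.85 against −2.51 to −2.36) and c3a.1 in replicate 4 at 1 h (4.29 against 4.19 to 4.2). At 6 h in WT they were cyp2x8 in replicate 3 (1.21 against 0.47 to 0.58), tnfa in replicate 2 (−7.26 against −6.42 to −6.28), stat3 in replicate 2 (0.62 against 0.06 to 0.15) and ier2a in replicate 1 (1.67 against 1.84 to 1.87).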

How the results depend on the processing

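Chosen after seeing the data were the tests without replicate 3 of WT at 0 h, apart from leaving out each array in turn, those with a replicate block within genotype or without that array, the named genes as background, and adjustment over the named genes only. Of the values of single named genes under other settings, 19875 kept their side of the threshold, 321 no longer passed and 83 passed only there. The 19875 include values that passed in neither setting, so this number does not measure how often calls held. Of those that passed in the main fit or under the other setting, 0 turned direction. Where neither passed, direction was not compared and could turn. For cul1a in WT at 1 h against 0 h it went from 0.10 to −0.03 without replicate 3 of WT at 0 h. The causes of the differences below were not tested, except that leaving out arrays, adjusting over fewer genes or asking for 2-fold changes the samples or genes that can pass. Dim probes limit what can be compared: signal was well above background in at most 77.4% of spots on all arrays but one. The miR-223 seed sites were not run.

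Counts of genes in KO against WT at 0, 1 and 6 h were 202, 91 and 124. At 0 h the count was 111 with quantile normalization, 134 at 2-fold, 494 with array weights, 41 over the named genes only and 28 in the compared groups alone. At 1 h it was 50 with normexp, 59 for probes above background on all arrays, 184 with array weights, 18 over the named genes only and 33 in the compared groups alone. At 6 h it was 66 with normexp, 234 with array weights, 17 over the named genes only and 66 in the compared groups alone. Same-numbered KO and WT arrays of a time share a slide, and their deviations correlated at 0 to 0.25, or 0.14 to 0.37 at 0 h without replicate 3 of WT. With the replicate block the count was 507 at 0 h and 194 at 6 h, and without that array as well 485, 302 and 422. Leaving out single arrays gave 106 to 239 at 0 h, 47 to 159 at 1 h and 71 to 202 at 6 h.

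For WT at 1 h against 0 h (11 genes) the count was 7 with no filter, 17 for probes above background on all arrays, 0 with the probes averaged (limma, 7918 at an unadjusted p under 0.05), 97 with array weights, 5 over the named genes only and 0 in the compared groups alone (2010). It was 30 with the replicate block without that array, 28 with the replicate block within genotype, and 5 to 63 without single arrays. For KO at 1 h against 0 h (7 genes) it was 2 with no filter, 1 with the probes averaged, 471 with array weights, 3 over the named genes only, 3 in the compared groups alone and 4 with the slide block. With the replicate block it was 4, without that array 241, with the replicate block within genotype and without that array 274, and without single arrays 2 to 61. For KO at 6 h against 0 h (0 genes with limma, 1680 at an unadjusted p under 0.05) it was 1 with median centring, 41 with array weights, 5 with the replicate block without that array, 44 with the replicate block within genotype without that array, and 0 to 1 without single arrays. For WT at 6 h against 0 h and for the differences in response leaving out single arrays gave 0 to 1, and the main counts there were 0, with 5835, 777 and 622 genes at an unadjusted p under 0.05.

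Of the 180 pairs of list and comparison 61 passed, and the number was 0 with an estimated correlation, 0 with fry, 34 with quantile normalization, 103 with no filter, 34 against the named genes as background and 39 to 79 without single arrays, the lowest being without replicate 3 of WT at 0 h and the highest without replicate 2 of WT at 0 h. In 19 pairs the call and its direction held with all arrays and without that array against either background at the preset correlation. Over the authors' lists 625 probes passed in the same direction, 1091 with the replicate block, and 771 without replicate 3 of WT at 0 h. The replicate block moved the other counts only from 91 to 114 for KO against WT at 1 h, from 11 to 15 for WT at 1 h against 0 h and from 61 to 64 for the lists, and those of 0 stayed at 0. Of list calls the block ended that of complement genes in KO against WT at 6 h (0.13) and in WT at 6 h against 0 h (0.0688). It added digestive organs in KO against WT at 1 h (0.0294) and 6 h (0.022), heat shock genes in KO against WT at 1 h (0.0211), erythroid genes in KO at 6 h against 0 h (0.0436) and macrophage markers in the response at 6 h (0.0454).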

Other observations

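The enrichment of chromosome 5, the direction of genes on single slides and the fits with a replicate block within genotype were tests chosen after the results had been seen.

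With the replicate number as a block within genotype and without replicate 3 of WT at 0 h, 274 genes passed in KO at 1 h against 0 h, 56 higher and 218 lower, and the count ranged from 1 to 471 over the other settings. With all arrays the block within genotype gave 10. In WT it gave 28 at 1 h with all arrays and 8 without that one, 1 of them named. At 6 h in WT 0 genes passed with limma in that fit, with 5031 at an unadjusted p under 0.05. Among the named genes, chosen here after their values were seen, cyp24a1, which inactivates vitamin D, was higher by 1.1 ± 0.12 (SE), the clock repressor nr1d1 by 1.31 ± 0.20, the AP-1 repressor jdp2b by 0.90 ± 0.12, atf3 by 0.86 ± 0.14 and klf3 by 0.62 ± 0.10. Lower were the collagen chaperone serpinh1b (−0.87 ± 0.13), the bone phosphatase phospho1 (−0.70 ± 0.09) and kera, a proteoglycan of the cornea (−0.68 ± 0.12). Of the 274 genes 266 had the same sign in WT. With limma 0 genes passed for the difference between the responses in that fit, and 1576 had an unadjusted p under 0.05.

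In the same fit 44 genes passed in KO at 6 h against 0 h, 6 higher and 38 lower, where the other settings gave 0 to 41. Higher were mmp9 by 1.01 ± 0.14 (adjusted p = 0.039) and the neuropeptide receptor npy1r by 1.37 ± 0.20 (adjusted p = 0.039), which was well above background on 1 of 4 KO arrays at 0 h. The proteoglycan kera (−0.87 ± 0.11) and phospho1 (−0.82 ± 0.08) were lower again, 2 of the 8 genes that passed at both times. All 44 had the same sign in WT, where mmp9 differed by 0.93.

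Of the 45 named genes that passed in KO against WT at any time, 12 (26.7%) were on chromosome 5, which holds miR-223, against 6.3% of the named genes tested (Fisher's exact test, two-sided, p = 1.6e-05, adjusted p = 4e-04 over the chromosomes). Their median distance from miR-223 was 179.5 genes against 421 for all 835 tested there (permutation test, one-sided, p = 0.014). Both tests took genes as independent, but some of the 12 lay close together. Distances were 89 and 90 genes for ankle2 and pgam5, and 174 to 190 for imp4, ppm1f, ypel1 and cldn26. Both p-values may therefore be too small. Variants carried along with the edited locus are a candidate explanation for part of the shared differences. The nearest of the 12 was 72 genes away, however, and 11 tested genes within 10 genes of miR-223 did not pass. A single slide is argued against by the 80 genes that passed at both 1 h and 6 h. They had the same direction (100%) on each slide at 0 h, at a median of 1.04 and 1.05 times their size at the later times. The 0 h arrays helped choose these genes through the shared spread, which limits the argument. The 91.6% at 0 h that passed again with slide as a block decide nothing, as slides balanced for genotype leave the estimates as they were. What stays open is the position on the slide, which cannot be told apart from genotype because all WT arrays lay at positions 1 and 3 and all KO arrays at 2 and 4, and sequence variants under single probes, as in 44.1% of 34 genes with further probes these moved by under 0.25 of the change and in 44.1% by over 0.5 of it, and an effect of the lost microRNA itself was not tested.

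Genes that rose at 1 h in both genotypes were weighed against scan day and the array that stood apart. Of the 12 genes that passed in either genotype 9 were higher, and their median rise was 1.64 on the slide scanned with the 0 h slides and 1.49 on the other, or 109.4%. The median rise in WT was 1.46 without replicate 3 of WT at 0 h against 1.47 with it, or 99.4%. Both values argue against these causes for these 9 genes, although the same arrays chose them, which favours genes that rose on both slides. A response to wounding, handling or the hour of collection, which may move immediate early and clock genes alike, stays open and was not tested.

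Other splits of the same arrays bear on each count. For KO against WT 1 of 35 splits, the real one, reached 91 genes at 1 h, where the highest other gave 3. At 6 h 1 of 35 reached 124, where the highest other gave 0, and at 0 h 1 of 35 reached 202, where it gave 7. These shares exclude chance only if neither replicate number nor slide ties the arrays. Deviations of same-numbered arrays, which share a slide, correlated at 0.07 to 0.24 at 1 h and at 0.01 to 0.25 at 6 h. At 0 h they correlated at 0.14 to 0.37 without replicate 3 of WT. Other arrays argue against chance: 79 of the 202 genes of 0 h passed again at 1 h and 105 at 6 h, and 200 had the same direction at either time. At both 1 h and 6 h 80 passed, all in the same direction. Same-numbered KO arrays deviate together over time, however, and the shared spread raises such overlaps. Among the 8 splits at each time that part every same-numbered pair, too few for a share under 0.05, the highest other gave 0. For WT at 1 h against 0 h 1 of 35 splits reached 11 genes and the highest other gave 2, which excludes chance only if the numbers do not pair the WT arrays. They do deviate together without replicate 3 at 0 h (correlations of 0.32 to 0.44), and the 8 splits that part every pair, where the highest other also gave 2, are too few for a share under 0.05. For KO at 1 h against 0 h 2 of 35 splits reached 7 genes and the highest other gave 169, so chance cannot be excluded on this count alone. Against chance stands that 6 of the 7 genes also passed in WT, on other arrays, where 0.0012 would be shared by independent lists. The lists are not independent, however, since WT and KO arrays of a time share slides and each gene's spread enters both comparisons. The split with 169 genes set replicate numbers 1 and 4 against 2 and 3 over both times and points to a structure of the samples. Among the 8 splits that part every pair of numbers, too few for a share under 0.05, the highest other gave 0. For KO at 6 h and WT at 6 h against 0 h the real count was 0, so all 35 of 35 splits reached it, and the highest others, 165 and 64, set numbers 1 and 4 against 2 and 3 as well. For the differences in response, also 0 at 1 h and 6 h, 100 of 100 splits reached it and the highest others were 643 and 288.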
